A study of Mus musculus with 4 samples.

How the data were processed

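The series holds 4 single-cell RNA libraries (10x Genomics Chromium 3′ chemistry), 2 from the M9 group and 2 from the C6M9 group, of CD8 T cells sorted on CD44 and CD90.1 from tumour-draining lymph nodes of mice, day 14. The deposited files are raw UMI counts per gene and cell barcode, one matrix per library, which the authors made with Cell Ranger 6.0.0 on mm10 according to their processing notes. The annotation release and whether intronic reads were counted are not given in the sources used here. Only barcodes that the authors kept as cells are listed, so the free RNA of empty droplets could not be measured. Of 32285 features, 32158 matched GENCODE mouse release 21 (GRCm38) by gene identifier, which gave the coordinates; all 78 genes named over all T cells matched. Which cells came from which mouse is not recorded, so the library was the replicate.

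Cells with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were kept, 10324 of 11113 barcodes. Doublets were scored per library with Scrublet in scanpy 1.11.5 (Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Its automatic threshold marked under 0.5% of the cells of each library, so the rule fixed for that case applied: the highest scores were left out at an expected rate of 0.8% per 1000 barcodes, 277 cells in all. The counts were scaled to 10000 per cell, log-transformed, and clustered without integration on 2000 variable genes, from which TCR and immunoglobulin variable genes, mitochondrial, ribosomal and sex genes had been left out. The clustering used 30 principal components, 15 nearest neighbours and Leiden resolution 0.6 (python-igraph 0.11.9, seed 7). A cluster took its name from 15 marker sets, as the set with most members among its 10 leading genes and the largest mean fold, with at least 3 markers of the set seen in at least 25% of its cells. For a cell type other than a T cell, 3 of the 10 leading genes had to be markers, a minimum set after the clusters had been seen. A cluster that met no rule kept its number. A cluster of 124 B cell-like cells was left out, which left 9923 T cells with 232 M UMIs (M, 1000000). Cluster 9 (331 cells) had 12 cells in M9 replicate 2, below the minimum of 50 per library, and was not tested. B cell-like cells were called free of T cells when 11 T cell genes summed to under 20 UMIs per 10000, a limit set after the values had been seen.

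Raw UMIs were summed per library over all T cells and over each class. Groups were compared as C6M9 minus M9 with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr, quasi-likelihood test with the trended dispersion as the base), two-sided, with Benjamini-Hochberg adjustment at 0.05 over all genes of a comparison. SEs are of the log2 difference. Levels are TMM-scaled UMIs per 1000000 (CPM). Whether the difference varied between the 6 classes was tested in edgeR over the class sums. The design held library, class and the product of class and group, so the 6 sums of a library shared its term. No replicate block was used in the main test, and whether like-numbered libraries share a batch is not known. With 2 libraries per group no sample could be tested as an outlier and no regrouping test could pass. Shares of cells were compared by an exact two-sided permutation test over libraries.

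The test was tried on simulated counts shaped like each comparison, with 100 genes changed by each fold and a single seed. With trended dispersion it recovered 45% of genes at 1.5-fold and 75% at 2-fold over all T cells, with 3.23% false calls. Within classes it recovered 10% (cluster 3) to 58% (cycling-like) at 1.5-fold and 51% to 76% at 2-fold, with 1.61% to 7.14% false calls. These simulations were added after a first set, with dispersions drawn gene by gene, gave 11.5% false calls over all T cells and 2.61% to 21.6% within classes. The share of false calls thus depends on the dispersion assumed.

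The 27 gene lists, 3 of them by name pattern, were fixed before the data were examined. They cover progenitor exhausted, naive and central memory, inhibitory receptor and exhaustion, cytotoxic effector, TCR signal induced, immediate early and dissociation stress, and interferon stimulated genes. They also cover S phase, G2 and M phase, glycolysis, cholesterol synthesis, oxidative phosphorylation, ribosomal protein and mitochondrial genome genes, cytokine receptor and JAK-STAT, homing and adhesion, MHC class I presentation, TCR complex and co-receptor, and apoptosis genes. The last group of lists marks other cells and mice: B cell, CD4 and regulatory T cell, NK and innate lymphoid, gamma delta T cell, myeloid and dendritic cell, red cell and platelet, melanoma and stroma, and the sex of the mice. Some genes stand in more than 1 list. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry. No camera call of any comparison held with an estimated correlation. With 2 libraries per group that correlation is estimated from 2 residual degrees of freedom, so the test can hardly pass. Its adjusted p, given beside each list, therefore cannot decide for or against the list, and the preset correlation is an assumption. The directional test of fry called only the CD4 and regulatory T cell list, over all T cells (adjusted p = 0.00731).

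Named genes over all T cells were the 12 with the largest log2 difference in each direction among those at an adjusted p under 0.05, at a mean of at least 10 CPM, with both libraries of one group above both of the other, leaving out predicted genes and receptor segments. To these were added 16 genes chosen beforehand and up to 4 members per list with the largest difference among those that passed, with no minimum level. Within a class the 5 largest in each direction were named by the same rule. Some genes that these rules select are not reported here, but count in every number of genes.

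Because the clusters rest on genes that differ between the groups, class shares were measured on clusters made again without the 1968 genes called in any comparison. For shares of cells with a transcript, each cell was thinned to 2000 UMIs; 9 and 5 cells of M9 and 2 and 8 cells of C6M9 lay below that depth and were left out of these shares. Intervals and limits from counts (95%, Wilson; 3 counts where none was seen) cover counting error only. The alternatives fixed beforehand were DESeq2 1.42.0 size factors, no filter on low counts, limma-voom, DESeq2's Wald test, a replicate block, leaving out each library, and doublets kept. Others were a stricter cell filter (1000 genes, 2000 UMIs, 5% mitochondrial), resolution 1.2, 1000 variable genes, variable genes without cycle genes, no cells in S or G2M phase, equal numbers of cells, counts thinned to the same total, and other cell types kept. Cells were also thinned to 1000 UMIs or not at all. The equal mixes of classes and subclusters with their random draws (5 draws each), TCR-activated-like cells without S and G2M phase, clusters from all variable genes, and every alternative for the class-by-group test were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.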

Results

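Single-cell transcriptomes were collected from CD8 T cells that had been sorted on CD44 and CD90.1 out of lymph nodes draining a tumour, 14 days after implantation in C57BL/6 mice. The series title places the study around progenitor exhausted CD8 T cells and their engagement of the T cell receptor (TCR). Its labels set a group called M9, with high affinity GP33, against a group called C6M9, with low affinity GP33; GP33 is a viral peptide that P14 T cells recognise. Each group had 2 libraries, and the library was the replicate (n = 2 per group throughout). The protocol pooled cells of 10 mice for M9 and 35 for C6M9 and does not say how they were divided, so the 2 libraries of a group may share mice, and each SD, SE and p here may then hold technical spread alone. The deposited matrices held 4586 and 1325 barcodes for M9 replicates 1 and 2, and 3220 and 1982 for C6M9 replicates 1 and 2. They held 79.2 M and 33.7 M unique molecular identifiers (UMIs; M stands for 1000000) for M9, and 73.4 M and 65.7 M for C6M9. The T cells kept numbered 4101 and 1199 in M9, with medians of 13205 and 20024 UMIs. In C6M9 they numbered 2889 and 1734, with medians of 13993 and 21476 UMIs.

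The first comparison asked which genes differed between low and high affinity over all T cells. Plac8, Il7r and Ly6c2 were among the genes higher in C6M9. Plac8 averaged 85.1 ± 8.45 CPM (TMM-scaled UMIs per 1000000; SD, n = 2) in M9 and 222 ± 4.0 in C6M9, a log2 difference of 1.39 ± 0.10 (SE, but adjusted p = 6.76e-04, edgeR). Il7r, the interleukin 7 receptor chain that sustains memory T cells, rose from 131 ± 15.5 to 268 ± 15.3 CPM, a log2 difference of 1.04 ± 0.11. Ly6c2, Ccl5 and Klre1, which encode a memory-associated surface protein, a chemokine and a lectin-like receptor of effector cells, rose by 1.10, 0.99 and 1.24 on the log2 scale. The other large rises were Mt1 (1.50), Bbc3 (1.09), S100a4 (1.09), Tsc22d3 (1.07), Galnt10 (1.03), Treml2 (0.92) and Epsti1 (0.88). UMIs of Ly6c2 can be shared with its close paralog Ly6c1.

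The OX40 ligand and receptor genes, Izumo1r and Egr2 were among the genes lower in C6M9. Tnfsf4, which encodes OX40 ligand, averaged 22.5 ± 6.59 CPM in M9 and 2.35 ± 0.04 in C6M9, a log2 difference of -3.27 ± 0.21 (SE, n = 2 per group, edgeR). Its receptor OX40, encoded by Tnfrsf4, differed by -3.06 ± 0.30, and Izumo1r, which encodes folate receptor 4, by -2.31 ± 0.12. The transcription factor genes Egr2 and Sox4 fell by 1.83 and 2.14 on the log2 scale, and Cd200, an inhibitory ligand gene, fell by 1.97. The remaining large falls were Rgs16 (-2.20), Gpm6b (-2.19), Cd22 (-2.07), Tiam1 (-1.99), Cxcl10 (-1.91) and Kcnc1 (-1.80). By the rule that named them, each of these 24 genes was higher in both libraries of one group than in both of the other. Of 13654 genes tested, 217 rose and 552 fell in C6M9, and 3264 had an unadjusted p under 0.05. The number of calls was 1402 without M9 replicate 1, 237 without C6M9 replicate 1, 1314 without M9 replicate 2 and 321 without C6M9 replicate 2. It was 1935 with no filter on low counts. Of 68 named genes that had passed, 26 lost their call without C6M9 replicate 1 and 17 without C6M9 replicate 2.

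The mix of cell classes differed between the groups and moved with this comparison. With each library drawn to the same number of cells of each class, a median of 144 genes was called over 5 draws, against 494 in random draws of as many cells; both draws were chosen after seeing the data. Of 68 named genes that had passed over all T cells, 32 passed in the equal mix and 54 in the random draws. Plac8, Il7r, Izumo1r, Tnfrsf4, Tox, Lag3 and Slamf6 were called in the equal mix, at median log2 differences of 0.95, 0.74, -1.66, -2.39, -0.67, -0.78 and -0.51. Tnfsf4, Sox4, Cd200 and Kcnc1 were also called, at -1.97, -1.36, -1.27 and -1.05, against -3.10, -2.11, -1.95 and -1.69 in random cells. Pdcd1, Cxcr5, Xcl1, Cd83, S1pr1 and Mt1 were not called in the equal mix, at -0.35, -0.31, -0.15, -0.41, 0.24 and 0.22. Nor were Ccl4, Ccl3, Rgs16, Tigit and Igfbp4, at -0.13, -0.76, -1.05, -1.31 and 0.57, or S100a4 and Treml2, at 0.61 and 0.51. Havcr2, Gzmb and Mki67, which had not passed, turned from 0.37, 0.41 and 0.34 to -0.26, -0.31 and -0.12.

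On the GRCm38 assembly, Plac8 (ENSMUSG00000029322) lies on chromosome 5 at 100553725 to 100572245, minus strand. Il7r (ENSMUSG00000003882) lies on chromosome 15 at 9505788 to 9530176, minus strand. Tnfsf4 (ENSMUSG00000026700) lies on chromosome 1 at 161395409 to 161418410, plus strand. Tnfrsf4 (ENSMUSG00000029075) lies on chromosome 4 at 156013843 to 156016612, plus strand. Izumo1r (ENSMUSG00000031933) lies on chromosome 9 at 14885814 to 14903949, minus strand. Slamf6 (ENSMUSG00000015314) lies on chromosome 1 at 171917515 to 171953170, plus strand. Tox (ENSMUSG00000041272) lies on chromosome 4 at 6686353 to 6991557, minus strand. The annotation gives all 7 as protein-coding genes, and 3′ UMIs were assigned to whole genes.

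**Figure D1:**
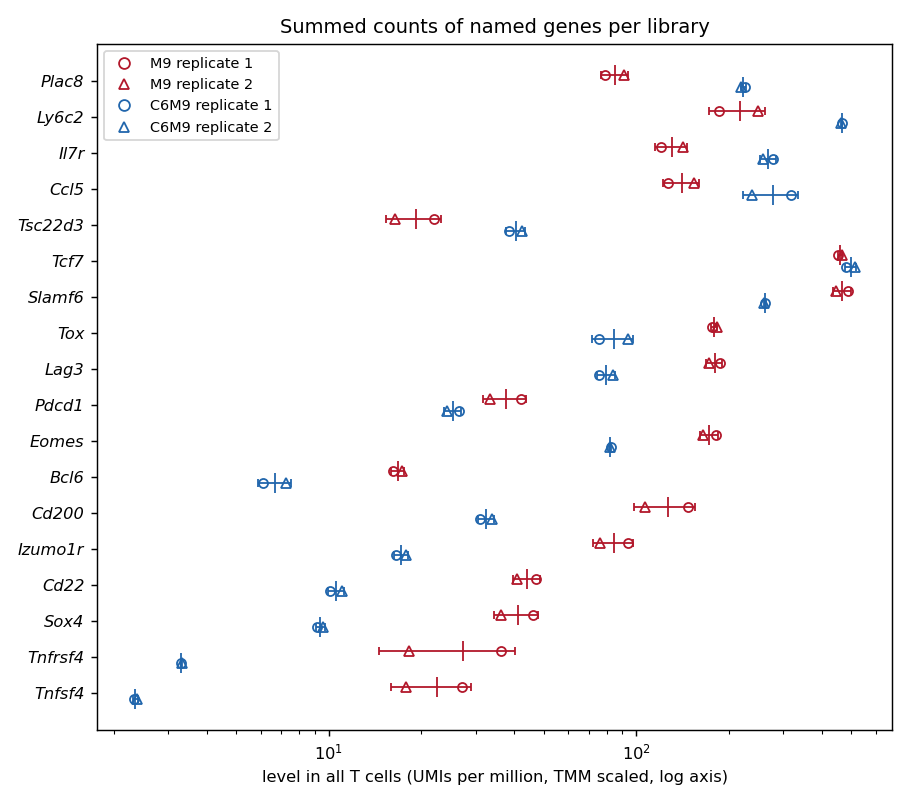
The horizontal log axis gives TMM-scaled UMIs per 1000000 in all T cells for a choice of the named genes (vertical); circles are replicate 1 and triangles replicate 2 of M9 (red) and C6M9 (blue), the tick is the mean and the bar the SD (n = 2). For Plac8 both C6M9 libraries lie above both M9 libraries, and for Tnfsf4 both lie below.

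Gene groups fixed before the data were examined were then compared over all T cells, in the order of exhaustion, memory and signalling. Of 19 progenitor exhausted genes, 13 fell and none rose, among them Slamf6 (467 ± 31.2 to 261 ± 1.84 CPM), Bcl6 (-1.32), Xcl1 (-1.34) and Cd200 (-1.97); adjusted over the list alone, 2 rose and 13 fell. Tcf7, the transcription factor gene most used to mark this state, was 459 ± 8.08 CPM in M9 and 497 ± 21.5 in C6M9 (log2 difference 0.11 ± 0.09, adjusted p = 0.483, edgeR). Id3 likewise did not pass (0.21, adjusted p = 0.233). The list's camera test gave an adjusted p of 1.92e-16 and adjusted p = 0.451 with an estimated correlation. Of 22 inhibitory receptor and exhaustion genes, 9 fell and 1 rose; adjusted over the list alone, 10 fell and 2 rose (camera adjusted p = 6.96e-10, but adjusted p = 0.451 with an estimated correlation). Tox, which programs exhaustion, fell from 179 ± 4.19 to 84.6 ± 13.1 CPM, and Lag3 from 179 ± 10.9 to 79.7 ± 5.51. Tigit (-2.13, from only 2.63 to 0.601 CPM), Tox2 (-1.56) and Pdcd1 (-0.58 ± 0.12, adjusted p = 0.0348, edgeR) also fell, and Cxcr6 (0.72) rose. Havcr2, a marker of terminal exhaustion, did not pass (0.37, adjusted p = 0.199).

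Of 30 genes induced by TCR signals, 11 fell and none rose; adjusted over the list alone, 18 fell and 1 rose (camera adjusted p = 1.06e-16, but adjusted p = 0.451 with an estimated correlation). Tnfrsf4, Cd200, Egr2 and Ccl4 (-1.77, but -0.13 and not called in the equal mix of classes) were among those that fell. Nr4a1, an immediate reporter of TCR signal, missed the threshold at -1.15 ± 0.27 (adjusted p = 0.0501, edgeR). It was at -0.45 in the equal mix of classes, against -1.06 in random cells. Ifng missed the threshold at -1.25 ± 0.56 (adjusted p = 0.229, edgeR). The M9 libraries were at 47.5 and 13.0 CPM for Ifng, and its difference was 0.02 without M9 replicate 1. None of 24 immediate early and dissociation stress genes passed, nor did any adjusted over the list alone (camera adjusted p = 0.0892).

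Of 20 naive and central memory genes, 7 rose and none fell; adjusted over the list alone, 14 rose (camera adjusted p = 2.22e-12, but adjusted p = 0.451 with an estimated correlation). Il7r, Ly6c2, S1pr1 (0.61), which guides exit from lymph nodes, and Igfbp4 (1.73, from only 0.958 to 3.16 CPM) were among those that rose. Of 29 cytokine receptor and JAK-STAT genes, 6 rose and 1 fell; adjusted over the list alone, 7 rose and 3 fell (camera up, adjusted p = 0.00878, but adjusted p = 0.451 with an estimated correlation). Il4ra (0.79) and Ifngr1 (0.55) rose, and Il10ra (-1.19) fell. Of 27 homing and adhesion genes, 5 rose and 5 fell; adjusted over the list alone, 8 rose and 8 fell, and camera did not pass (adjusted p = 0.947, upward, with a median log2 difference of -0.02). Cxcr5 (-0.91) and Ccr6 (-1.49, from only 1.13 to 0.393 CPM) were among those that fell. Of 26 cytotoxic effector genes, 7 rose and 3 fell; adjusted over the list alone, 9 rose and 4 fell (camera up, adjusted p = 0.00878, but adjusted p = 0.747 with an estimated correlation). Klre1 and S100a4 rose, Ccl3 (-1.77) and Ccl4 fell, and Gzmb (0.41, adjusted p = 0.376), Cx3cr1 (-0.16, adjusted p = 0.702, but 0.16 without M9 replicate 1) and Klrg1 (0.20, adjusted p = 0.799) did not pass.

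Of 42 S phase genes, 5 rose, among them Rrm2 (0.65), Exo1 (0.62), Cdc45 (0.53) and Tyms (0.44); adjusted over the list alone, 28 rose (camera adjusted p = 7.64e-13, but adjusted p = 0.667 with an estimated correlation). Of 52 G2 and M phase genes, 5 rose, including Birc5 (0.61), Ccnb2 (0.55), Tubb4b (0.53) and Cdca3 (0.49), and Mki67 did not pass (0.34, adjusted p = 0.253); adjusted over the list alone, 18 rose (camera adjusted p = 2.25e-11, but adjusted p = 0.667 with an estimated correlation). In the equal mix of classes none of these 8 was called, with Rrm2, Exo1, Cdc45 and Tyms at 0.20, 0.17, 0.14 and 0.05 and Birc5, Ccnb2, Tubb4b and Cdca3 at 0.14, 0.12, 0.14 and 0.03, against 0.39 to 0.64 in random cells. Nor did any of them pass in cycling-like cells, from -0.07 (Tyms) to 0.10 (Rrm2). Without cells called in S or G2M phase, Exo1 and Cdc45 turned to -0.52 and -0.15. Of 20 glycolysis genes only Hk2, the gene of hexokinase 2, passed and it fell (-0.54), over all genes and adjusted over the list alone, while the list's camera test pointed up (median 0.21, adjusted p = 0.00299, but adjusted p = 0.451 with an estimated correlation). Of 89 oxidative phosphorylation genes Sdhd alone rose (0.34), and none did adjusted over the list alone (camera up, adjusted p = 1.23e-06, but adjusted p = 0.747 with an estimated correlation). None of 81 ribosomal protein genes passed either way (camera up, adjusted p = 1.42e-04, but adjusted p = 0.747 with an estimated correlation). None of 23 cholesterol synthesis genes (camera adjusted p = 0.324) or 13 mitochondrial genome genes (camera adjusted p = 0.958, downward, median 0.01) passed, over all genes or adjusted over the list alone.

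Of 40 interferon stimulated genes, Oasl2 (0.73) and Ifi47 (0.47) rose and Cxcl10, which encodes a chemokine, fell; adjusted over the list alone, 13 rose and 4 fell (camera up, adjusted p = 0.00878, but adjusted p = 0.789 with an estimated correlation). Of 18 MHC class I presentation genes Psmb10 (0.39) rose, also adjusted over the list alone (camera adjusted p = 0.4). Of 22 TCR complex and co-receptor genes Fyn (-0.55) fell, and 2 fell adjusted over the list alone (camera adjusted p = 0.333). Of 22 apoptosis genes Bbc3, which encodes the death promoter PUMA, rose, and 3 fell, among them Bcl2a1d (-1.16) and Bcl2a1b (-0.80); adjusted over the list alone, 2 rose and 4 fell (camera adjusted p = 0.333). UMIs of the Bcl2a1 paralogs can be exchanged between them.

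Markers of other cell types were measured in the same T cells. Of 15 B cell genes Ighd (0.85) and Ighm (0.50) rose; adjusted over the list alone, 3 rose and 1 fell (camera up, adjusted p = 0.00878, but adjusted p = 0.604 with an estimated correlation). The B cell-like cells left out numbered 27 and 12 in M9, and 45 and 40 in C6M9. Of 7 CD4 and regulatory T cell genes, Izumo1r, Ikzf2 (-0.78) and Cd4 (-1.26, from 2.70 ± 0.659 to 1.14 ± 0.09 CPM) fell. Adjusted over the list alone, 4 fell (camera adjusted p = 1.34e-06, but adjusted p = 0.451 with an estimated correlation). Izumo1r leads cluster 3, where Cd8a was seen in 58.9% of M9 and 64.4% of C6M9 cells at equal depth. Ikzf2 also stands in the progenitor exhausted list, so neither gene marks CD4 T cells alone here. Of 8 NK and innate lymphoid genes Klrb1c (-1.53) and Eomes (-1.07), which CD8 T cells also express, fell; adjusted over the list alone, 3 fell (camera adjusted p = 0.00798, but adjusted p = 0.451 with an estimated correlation). Of 12 myeloid and dendritic cell genes Cd68 (-0.93) fell; adjusted over the list alone, 2 rose and 1 fell (camera adjusted p = 0.539). None of 6 gamma delta T cell genes passed, and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.947, upward, median -0.20). None of 4 melanoma and stroma genes (camera adjusted p = 0.607) or 4 genes of the sex of the mice (camera adjusted p = 0.277) passed. The red cell and platelet list had 1 measured gene, at -0.09, and was not tested.

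The next comparison asked how the T cells divided into classes. Classes were clusters named by their leading genes: memory-like (Il7r, Ccl5, S1pr1), TCR-activated-like (Tnfrsf4, Cd83, Xcl1), interferon-like (Ifit3), effector-like (Klre1) and cycling-like, and cluster 3, led by Izumo1r, Cd22 and Sox4, kept its number. The name effector-like rests on killer lectin-like receptor genes (Klre1, Klrc2, Klrc1, Klrk1, Klrd1) and Zeb2: at equal depth Gzmb was seen in 0.751 and 0.757% of these cells in M9 and C6M9, Cx3cr1 in 1.37 and 0.673% and Klrg1 in none, but Tcf7 in 73.5 and 70.3%. Shares come from clusters made without the 1968 genes called in any comparison, each named by the class that most of its cells had. Genes that differed without a call could stay in, so these shares are not independent of the expression differences. Memory-like cells were 9.44 ± 3.04% of T cells in M9 and 31.1 ± 7.49% in C6M9 (SD, n = 2). Cluster 3 went the other way, at 30.7 ± 4.06% in M9 and 10.1 ± 4.06% in C6M9, as did TCR-activated-like cells, at 20.8 ± 7.09% and 5.69 ± 1.58% (9.55 ± 3.12% and 3.19 ± 0.643% with doublets kept). Cycling-like cells were 18.2 ± 2.38% and 25 ± 0.286%, effector-like cells 9.38 ± 1.47% and 13.6 ± 1.37%, and interferon-like cells 10.1 ± 4.97% and 12.2 ± 1.28%. The last difference, of 2.12 points, lies within the spread of the M9 libraries and was -1.40 without M9 replicate 1 and 5.63 without M9 replicate 2, and only 58.4% of the cells behind it had been interferon-like. In clusters from all variable genes, chosen after seeing the data, that share was 4.85 and 6.84% in M9, and 7.41 and 8.02% in C6M9. Cluster 9, led by Gzma, was 1.34 ± 0.721% and 2.27 ± 0.515%, a difference of 0.924 points that was 0.414 without M9 replicate 2 and 1.43 without M9 replicate 1, and 2.05 to 2.48 under other clusterings or cell filters. Except for interferon-like cells, both libraries of one group lay above both of the other, by little in cluster 9 (1.90% in C6M9 replicate 2 against 1.85% in M9 replicate 1). The exact two-sided permutation test of 2 against 2 libraries cannot go below p = 0.333, so these shares are given as values.

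**Figure D2:**
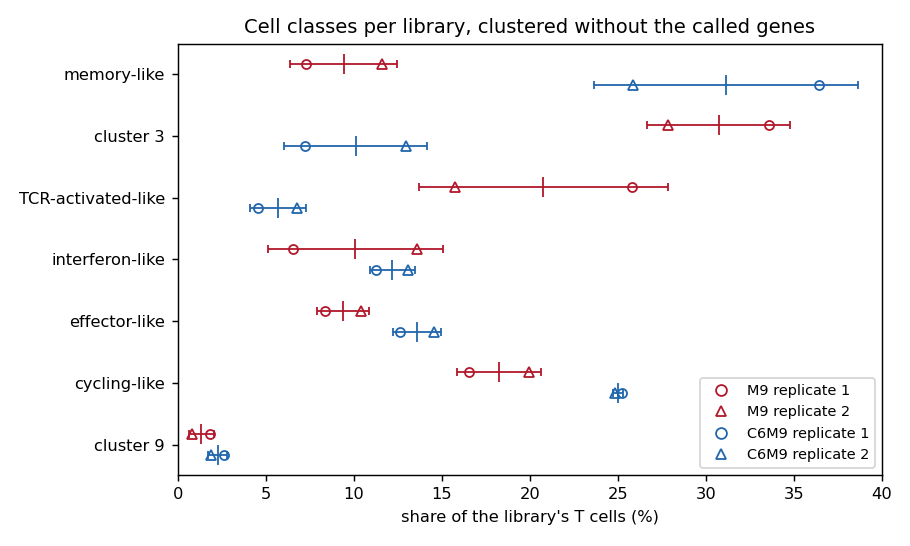
The horizontal axis gives the percent of each library's T cells in each class (vertical), from clusters made without the called genes; circles are replicate 1 and triangles replicate 2 of M9 (red) and C6M9 (blue), with mean and SD (n = 2). Memory-like cells average 31.1% in C6M9 and 9.44% in M9, and cluster 3 averages 10.1% and 30.7%.

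At an equal depth of 2000 UMIs per cell, Il7r was seen in 22.4 ± 2.90% of M9 T cells and 41.6 ± 1.60% of C6M9 T cells (SD, n = 2; 58.5% and 83.2% before thinning). Slamf6 was seen in 59.7 ± 2.65% and 39.1 ± 0.107% (97.2% and 91.4%), Tox in 33.1 ± 2.74% and 16.9 ± 2.11% (89.1% and 71.3%), and Lag3 in 29.9 ± 0.179% and 13.1 ± 1.63% (82.1% and 61.5%). Tcf7 was seen in 62.4 ± 4.04% and 60.4 ± 0.685%, a difference within the spread of the M9 libraries (97.8% and 97.4%). As background, B cell-like cells with few T cell transcripts had a median of 4434.5 UMIs in M9 (22 cells) and 4898 in C6M9 (41 cells). Among those of M9, Il7r, Tox and Lag3 were seen in none, which allows a share of up to 13.6%, and Tcf7 in 4.55%. In those of C6M9 the shares were 7.32% for Il7r, 2.44% for Tox, 4.88% for Lag3 and 2.44% for Tcf7. Slamf6, which B cells express, was seen in 31.8% and 39.0% of them. Cells called in S or G2M phase at equal depth made up 35.8 ± 1.90% of M9 and 39.1 ± 0.449% of C6M9 (exact permutation p = 0.333, the smallest possible, as for each share here), and whether free RNA takes part in these calls is open. That difference of 3.38 points was 6.03 with doublets kept, 6.02 with the stricter cell filter, 4.92 at 1000 UMIs and 7.85 without thinning, and 2.03 without M9 replicate 1.

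The comparison was repeated within each class, to ask which differences also appeared there. A class can still hold cells of unlike state. List members named within a class, beyond the 5 largest changes each way, were chosen after their values were seen. In memory-like cells 6 genes rose and 35 fell in C6M9 of 10735 tested (edgeR), with 977 at an unadjusted p under 0.05. Plac8 rose by 0.78 ± 0.11 (SE, n = 2 per group) and Il4ra, the interleukin 4 receptor chain, by 0.82 ± 0.14, along with Tsc22d3 (0.75), Bbc3 (0.99, which is also among the genes that lead this cluster) and Hspa1a (0.96). Izumo1r fell by 1.72 on the log2 scale, from 64.6 ± 8.23 to 19.7 ± 1.93 CPM, and Cd200 (-1.53), Wnt10a (-1.56), Egr2 (-1.47) and Sox4 (-1.16) fell too. Of 28 genes induced by TCR signals 3 fell, namely Egr2, Egr3 (-0.88) and Cd200; adjusted over the list alone, 7 fell (camera adjusted p = 1.06e-05, but adjusted p = 0.596 with an estimated correlation). Of 20 inhibitory receptor and exhaustion genes Lag3 (-0.94) fell; adjusted over the list alone, 7 fell and 2 rose (camera adjusted p = 8.05e-05, but adjusted p = 0.426 with an estimated correlation). Of 23 immediate early and dissociation stress genes Hspa1a rose, and 2 rose adjusted over the list alone (camera up, adjusted p = 3.41e-05, but adjusted p = 0.754 with an estimated correlation). The number of calls was 288 without M9 replicate 1 and 134 without M9 replicate 2, and 156 with no filter on low counts, 86 with doublets kept, 114 at the finer clustering and 70 without cycle genes in it.

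In cluster 3 cells, 8 genes rose and 8 fell of 9894 tested (edgeR), with 736 at an unadjusted p under 0.05. Il7r rose from 127 ± 14.9 to 298 ± 3.07 CPM (log2 difference 1.23 ± 0.13, n = 2 per group). Plac8 (1.86), Bbc3 (1.54), Ccl5 (1.34) and Il18r1, an interleukin 18 receptor gene (1.25), rose too. Il7r, Ccl5 and Bbc3 are also among the genes that lead the memory-like cluster. Whether memory-like cells were assigned to cluster 3 in C6M9 was not tested. Tnfsf4 (-2.53), Pmepa1 (-2.08), Setbp1 (-1.96) and Cd200 (-1.19) fell, as did Izumo1r (-2.08), which also defines the cluster. Of 18 naive and central memory genes Il7r and Ly6c2 (1.16) rose; adjusted over the list alone, 7 rose (camera adjusted p = 4.01e-10, but adjusted p = 0.386 with an estimated correlation). The C6M9 libraries had 109 and 92 cells here against 1531 and 358 in M9. The number of calls was 125 without M9 replicate 1, 39 without M9 replicate 2 and 4 without C6M9 replicate 2, and between 7 (limma-voom) and 73 (no filter on low counts) under the other settings.

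TCR-activated-like cells differed in 1548 genes of 9963 tested, 864 higher and 684 lower in C6M9 (edgeR; 2958 at an unadjusted p under 0.05). Of 41 S phase genes 30 rose, such as Exo1 (1.74 ± 0.30, SE, n = 2 per group), Cdc45 (1.42) and Rrm2 (1.12); adjusted over the list alone, 37 rose (camera adjusted p = 7.75e-26, but adjusted p = 0.197 with an estimated correlation). Of 18 glycolysis genes 8 rose, such as Mif (0.83) and Ldha (0.76), the gene of lactate dehydrogenase A; adjusted over the list alone, 12 rose (camera adjusted p = 6.6e-06, but adjusted p = 0.197 with an estimated correlation). Of 23 cholesterol synthesis genes 6 rose, such as Idi1 (1.57) and Fdps (1.07); adjusted over the list alone, 7 rose (camera adjusted p = 1.79e-05, but adjusted p = 0.197 with an estimated correlation). Of 88 oxidative phosphorylation genes 20 rose; adjusted over the list alone, 22 rose (camera adjusted p = 5.05e-08, but adjusted p = 0.467 with an estimated correlation). Plac8 (2.08), Ly6c2 (1.55), Lmo4 (1.65) and Olfr1369-ps1 (2.53) were the other large rises.

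In the same cells, of 29 genes induced by TCR signals 15 fell and 2 rose. Nr4a2 (-2.57), Egr2 (-1.53) and Egr1 (-1.19) were lower and Irf8 (0.80) and Myc (0.52) higher. Adjusted over the list alone, 17 fell and 2 rose (camera adjusted p = 2.48e-12, but adjusted p = 0.197 with an estimated correlation). Tnfrsf4, Tnfrsf9, Egr3 and Cd200 of this list lead the class itself, as do Cd83 and Xcl1 of the progenitor exhausted list. Of 20 inhibitory receptor and exhaustion genes 11 fell and 1 rose, such as Ctla4 (-1.52), Lag3 (-1.19) and Tox (-0.95) lower and Cxcr6 (1.09) higher; adjusted over the list alone, 15 fell and 1 rose (camera adjusted p = 2.25e-09, but adjusted p = 0.203 with an estimated correlation). Of 19 progenitor exhausted genes 12 fell and 1 rose, such as Slamf6 (-0.91) and Bcl6 (-0.97) lower; adjusted over the list alone, 13 fell and 3 rose (camera adjusted p = 1.36e-09, but adjusted p = 0.197 with an estimated correlation). Penk (-2.98), Izumo1r (-2.52), Dock4 (-2.19) and Ifng (-1.66) fell, as did Tnfrsf4 (-3.48), which also defines the class. Of 7 B cell genes 4 fell, among them H2-Ab1 (-4.69 ± 0.76), H2-Aa (-2.43 ± 0.51) and Cd74 (-1.04 ± 0.18), which other antigen-presenting cells share, and Ighm (0.35) rose; adjusted over the list alone, 4 fell and 1 rose (camera adjusted p = 0.017, but adjusted p = 0.467 with an estimated correlation). Of 4 myeloid and dendritic cell genes Cd68 (-1.94 ± 0.33) fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.526). Cd4 fell by 2.61 on the log2 scale. The number of calls was 474 without C6M9 replicate 1 and 908 without C6M9 replicate 2, and 757 with DESeq2. It was 648 without cells called in S or G2M phase, and a median of 175 over 5 draws with an equal mix of the class's subclusters, against 685 in random draws of as many cells, all chosen after seeing the data.

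In interferon-like cells 13 genes rose and 46 fell of 9230 tested (edgeR), with 1149 at an unadjusted p under 0.05. Il7r rose from 180 ± 26.8 to 416 ± 96.2 CPM (log2 difference 1.21 ± 0.16, n = 2 per group), and Rras2 (1.15), Tsc22d3 (1.05), Ccl5 (1.02) and Il18r1 (0.94) rose. Izumo1r (-2.60), Sox4 (-2.44), Cd22 (-2.29) and Gzmk (-2.28), a granzyme gene, fell. Of 19 progenitor exhausted genes 5 fell, such as Xcl1 (-1.37), Myb (-1.05) and Slamf6 (-0.74); adjusted over the list alone, 12 fell and 1 rose (camera adjusted p = 1.86e-12, but adjusted p = 0.387 with an estimated correlation). Of 40 interferon stimulated genes, many of which define the class, 3 fell, among them Cxcl10 (-1.29) and Ifih1 (-0.77); adjusted over the list alone, 15 fell (camera adjusted p = 8.39e-13, but adjusted p = 0.388 with an estimated correlation). Without M9 replicate 2 the calls numbered 192, and they numbered between 32 (stricter cell filter) and 244 (no filter on low counts) under the other settings.

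In effector-like cells 26 genes rose and 58 fell of 10040 tested (edgeR), with 1404 at an unadjusted p under 0.05. Gzmm, a granzyme gene, rose from 6.01 ± 1.31 to 20.3 ± 2.19 CPM (log2 difference 1.71 ± 0.25, n = 2 per group), and Fgl2 (1.27), Birc5 (1.24), the chemokine receptor gene Ccr2 (1.2) and Ncald (1.12) rose. Tiam1 (-2.54), Tnfrsf4 (-1.94), Gpm6b (-1.52), Nt5e (-1.51), which encodes CD73, and Sox4 (-1.38) fell. Of 24 cytotoxic effector genes 4 rose, including S100a4 (0.89) and S100a6 (0.67); adjusted over the list alone, 9 rose and 1 fell (camera adjusted p = 6.83e-08, but adjusted p = 0.401 with an estimated correlation). Of 19 progenitor exhausted genes 4 fell, such as Bcl6 (-0.99) and Ikzf2 (-0.61); adjusted over the list alone, 7 fell and 1 rose (camera adjusted p = 2.3e-05, but adjusted p = 0.401 with an estimated correlation). The number of calls was 711 without M9 replicate 1 and 40 without C6M9 replicate 1, and between 16 (clusters without cycle genes) and 228 (no filter on low counts) under the other settings.

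In cycling-like cells 57 genes rose and 64 fell of 12050 tested (edgeR), with 1490 at an unadjusted p under 0.05. Ccl5 rose from 25.1 ± 3.63 to 112 ± 3.47 CPM (log2 difference 2.15 ± 0.11, n = 2 per group) and Il7r from 59.7 ± 5.66 to 163 ± 14.8 (1.45 ± 0.11), with Tsc22d3 (1.15), Plac8 (1.12) and Ifit1 (0.99). Gzmk (-1.74), Sox4 (-1.54), Gpm6b (-1.38), Tiam1 (-1.36) and Alcam (-1.34) fell. Of 19 naive and central memory genes 5 rose, such as Il7r, Ly6c2 (0.81) and the homing receptor gene Ccr7 (0.54); adjusted over the list alone, 17 rose (camera adjusted p = 6.34e-26, but adjusted p = 0.482 with an estimated correlation). Of 39 interferon stimulated genes 7 rose and Cxcl10 (-1.35) fell; adjusted over the list alone, 26 rose and 1 fell (camera adjusted p = 2.61e-19, but adjusted p = 0.482 with an estimated correlation). Of 14 B cell genes Cd79a (1.75 ± 0.31), Ighd (1.05) and Ighm (0.52) rose. Adjusted over the list alone, 10 rose (camera adjusted p = 1.84e-14, but adjusted p = 0.482 with an estimated correlation). At equal depth Cd79a was seen in 0% of cycling-like cells in both M9 libraries, and in 0.416 and 0.456% in C6M9. B cell-like cells with T cell transcripts, left out here, numbered 12 and 5 in M9 and 25 and 19 in C6M9. The cause of these rises was not tested. Calls numbered 309 without M9 replicate 1, 184 without M9 replicate 2 and 63 without C6M9 replicate 2, and 639 with no filter on low counts.

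Across the 6 classes, Plac8 rose in all 6, and Ccl5, Il7r, Ly6c2 and Tsc22d3 rose in 4. Cd200 and Izumo1r fell in all 6, and 18 further genes fell in 4 or 5. Among these were Sox4, Gpm6b, Alcam and Cd22 in 5, and Tox, Lag3, Tnfrsf4 and Tnfsf4 in 4. Il7r and Ccl5 also lead the memory-like cluster, and Izumo1r, Cd22 and Sox4 lead cluster 3. Whether the mix of such cells inside interferon-like, effector-like or cycling-like cells differed between the groups was not tested. A test of the difference itself, with class and group together in edgeR, found 1514 of 10975 genes whose group difference varied between classes. This number was 893 without M9 replicate 1, 913 without C6M9 replicate 1, 961 without M9 replicate 2 and 500 without C6M9 replicate 2. Ly6c2 ranged from 0.31 in memory-like to 1.55 in TCR-activated-like cells, and Eomes from -0.87 in interferon-like to 0.23 in memory-like cells.

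**Figure D3:**
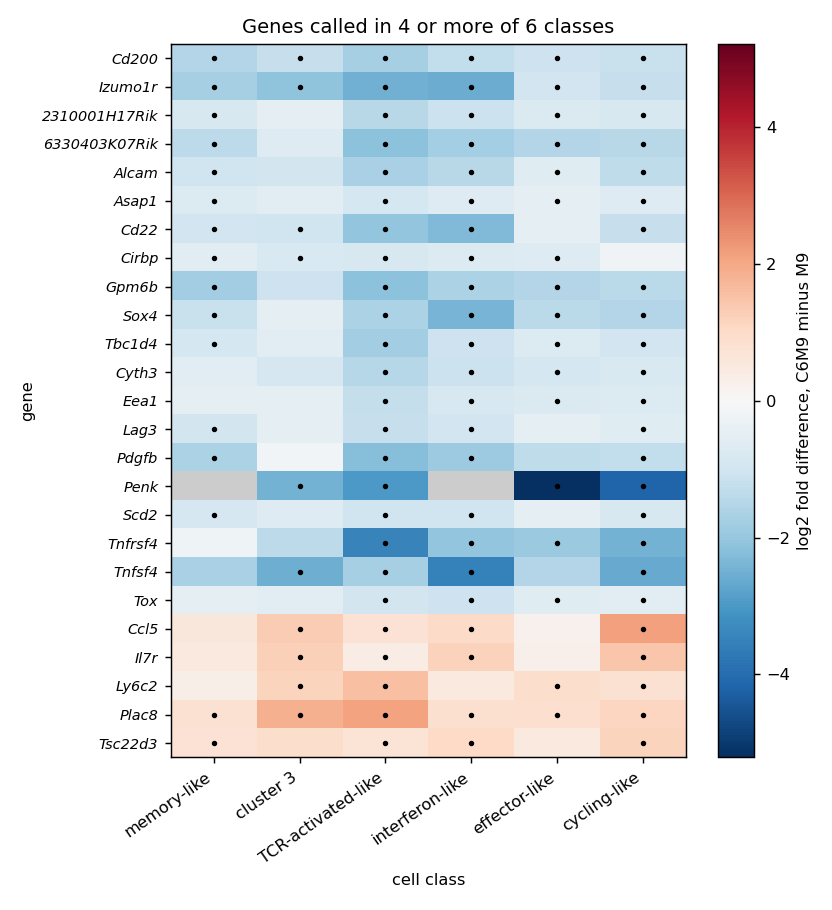
Colour gives the log2 difference, C6M9 minus M9, of each gene called in 4 or more of 6 classes (vertical) in each class (horizontal); a dot marks an adjusted p under 0.05 and grey a gene not tested there. Plac8 carries a dot in 6 classes and Tnfrsf4 is lowest in TCR-activated-like cells, at -3.48.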

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

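The tests of free RNA, the draws with an equal mix of classes or subclusters, and the run of TCR-activated-like cells without cells called in S or G2M phase and its test were chosen only after the results they bear on had been seen. The test of whether the group difference varied between classes stands beside the planned comparisons; its alternatives were chosen after seeing the data.

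The difference between C6M9 and M9 itself differed between the 6 cell classes for 1514 of 10975 genes, by a test of the product of class and group in edgeR at an adjusted p under 0.05. The number was 893 without M9 replicate 1, 913 without C6M9 replicate 1, 961 without M9 replicate 2 and 500 without C6M9 replicate 2. Of 77 named genes in that test 44 passed, and 42 of these are described. Each value that follows is the span between the lowest and highest class difference (log2, over the classes where the gene was tested). A span joins the extremes of up to 6 estimates, so noise widens it. Klre1 ran from -1.06 ± 0.67 (SE), not called, to 3.35 ± 0.65. Neither end was called for Rrm2 (-0.03 ± 0.55 and 2.65 ± 0.71), Cdca3 (-1.15 ± 0.76 and 1.12 ± 0.41) or Mki67 (-0.40 ± 0.30 and 0.63 ± 0.24). The ends of Il7r had smaller SEs, at 0.26 ± 0.11 and 1.45 ± 0.11.

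Among genes higher in C6M9 over all T cells, the spans were 1.30 for Plac8, 4.41 for Klre1, 1.24 for Ly6c2, 1.72 for Bbc3, 1.03 for S100a4, 1.19 for Il7r, 1.91 for Ccl5, 0.60 for Epsti1, 1.81 for Igfbp4, 0.81 for S1pr1, 1.02 for Cxcr6 and 0.57 for Ifi47. Il7r was at 0.26 in effector-like and 1.45 in cycling-like cells. Cell cycle genes spanned 2.68 (Rrm2), 1.69 (Exo1), 1.41 (Cdc45), 0.69 (Tyms), 1.52 (Birc5), 1.29 (Ccnb2), 0.93 (Tubb4b), 2.27 (Cdca3) and 1.04 (Mki67). Exo1 and Cdc45 were tested in 2 classes, at 0.06 and 0.01 in cycling-like and 1.74 and 1.42 in TCR-activated-like cells.

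Among genes lower in C6M9, the spans were 3.27 for Tnfrsf4, 1.59 for Izumo1r, 1.74 for Rgs16, 1.93 for Sox4, 1.77 for Cd22, 0.65 for Cd200, 1.72 for Kcnc1, 0.74 for Slamf6, 0.66 for Pdcd1, 0.60 for Tox, 0.73 for Lag3, 1.81 for Xcl1, 1.46 for Il10ra, 0.56 for Fyn, 0.56 for Bcl2a1b, 0.76 for Ikzf2, 1.10 for Eomes and 2.21 for Cd68. Of the remaining genes, Tcf7 spanned 0.32, Ighm 0.47 and Sdhd 0.51.

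Some cells of the sort stood outside the comparisons, except where other cell types were kept as an alternative. The sort for CD8 T cells held 124 B cell-like cells, 27 and 12 in M9 and 45 and 40 in C6M9. Of these, 63 held few T cell transcripts (median 4801 UMIs) and 61 held T cell transcripts as well (median 27924 UMIs).

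The first pattern weighed is the 769 genes called over all T cells, which number 237 without C6M9 replicate 1, 321 without C6M9 replicate 2, 1402 without M9 replicate 1 and 1314 without M9 replicate 2. Unequal depth as the whole source is argued against, since thinning every library to the same total left 0.900 times the calls. A different mix of cell classes may account for part of them: equal mixes called 109 to 158 genes and random draws of as many cells 418 to 718, a ratio of medians of 0.291. That lies between the bounds set in advance for a whole source (under 0.25) and for none (0.75 or more), and class and group cannot be told apart here, because the classes rest partly on the called genes. An effect of GP33 affinity within cells stays open and untested, since each group is 1 affinity.

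The second pattern is the 1548 genes called in TCR-activated-like cells, which number 474 without C6M9 replicate 1 and 908 without C6M9 replicate 2. A different mix of subclusters inside the class may account for part of them, as equal mixes called 84 to 233 genes and random draws of as many cells 351 to 890, a ratio of medians of 0.255. That lies just above the bound of 0.25 set for a whole source, so the mix cannot be told apart from a change within cells. Cells in S or G2M phase as the whole source are argued against: without them 648 genes were called in fewer cells, but the 1439 called genes outside the 2 lists that call the phases kept a median log2 difference of 0.56 against 0.65, a ratio of 0.859, and 72.1% of them kept 0.75 or more of their own. For the S phase genes this source stays open, since the test written beforehand, on their own list, was dropped because the phases are called from them, and affinity stays open as well.

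The third pattern is the 20 genes lower in C6M9 in 4 or more of 6 classes. Free RNA from M9 cells may account for some of them: in 22 B cells of M9 (115111 UMIs) their median level was 0.228 of that in the M9 class where each was lowest, with 100 UMIs seen against 113 expected at that level, but Cd22 and Cirbp, which B cells express, gave 25 UMIs each and Izumo1r gave 0. For Lag3 and Tox free RNA as the whole source is argued against, since 26.6 UMIs were expected at that level and none was seen, an upper limit of 0.113 of those expected. The bound against it for these 2 genes, under 0.25, was set after seeing the data. It is looser than the bound for the 20 genes together, which 0.113 would not have met. Cells of cluster 3 within the M9 memory-like class bear on the memory-like comparison alone, and Izumo1r was at -2.08 in cluster 3 itself. In memory-like cells they could lower these genes, at a needed share of 28.3%, and cannot be told apart from a change within cells: 43 other leading genes of that cluster had a median of -0.19 (quartiles -0.38 to -0.03), outside which lies the -0.50 expected at that share, but the ratio of 0.373 is above the 0.25 set as the bound against, and affinity stays open.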

How the results depend on the processing

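Among these alternatives, the equal mixes, the random draws, the TCR-activated-like cells without S and G2M phase, the clusters from all variable genes and all alternatives of the class-by-group count were chosen after seeing the data. The differences in class shares moved by less than the SD between libraries in 66 of 76 cases, that of the phase share in 5 of 9 and those of transcript shares in 113 of 144. Counts of called genes stayed within 1.5 times in 50 of 98 cases and counts of called lists in 78 of 94. Named genes over all T cells counted as the same in 1163 cases, lost the call in 130, gained it in 21, moved in 7 and turned in 2. The same meant an equal direction and side of the threshold. An uncalled gene that changed sign by less than its SE, and an uncalled list that changed direction, also counted as the same. Within classes 708 counted as the same and 84 lost the call. Single lists counted as the same in 1978 cases, lost the call in 264, gained it in 69 and turned in 1. Clusters without cycle genes formed no interferon-like cluster once the called genes were withheld, so that share has no value there. With 1 library left in a group, its spread was taken as that of the other group. No scaling moved the median of all genes by over 0.0242 (log2).

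Without a filter on low counts the genes called were 1935 over all T cells, 156 in memory-like, 73 in cluster 3, 244 in interferon-like, 228 in effector-like and 639 in cycling-like cells, and 14 lists in effector-like cells; more genes are tested there. DESeq2's Wald test gave 757 in TCR-activated-like and 34 in interferon-like cells, its size factors 94 in interferon-like cells, and limma-voom 7 in cluster 3. With doublets kept the counts were 86 in memory-like, 9 in cluster 3 and 51 in effector-like cells. The stricter cell filter gave 32 in interferon-like and 49 in effector-like cells. Resolution 1.2 gave 114 in memory-like, 9 in cluster 3, 144 in interferon-like and 44 in effector-like cells. Variable genes without cycle genes gave 70, 33, 210 and 16 in the same 4 classes. Equal class mixes gave 144 over all T cells and random cells 494; in TCR-activated-like cells an equal subcluster mix gave 175, random cells 685 and leaving out S and G2M cells 648, all with fewer cells. Apart from those with more genes or fewer cells, the cause was not tested.

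Called lists fell to 0 with an estimated correlation in all 7 comparisons, where 2 libraries per group leave that test hardly able to pass. With fry's directional test they fell to 1 over all T cells and 0 within each class. Its mixed test, which ignores direction, called 13 lists over all T cells and 20 in TCR-activated-like cells. It called 6 in memory-like, 2 in cluster 3, 0 in interferon-like, 1 in effector-like and 5 in cycling-like cells. Without S and G2M cells Exo1 turned to -0.52 and Cdc45 to -0.15, where the cells that express them were removed. In cluster 3 the immediate early and dissociation stress list turned down without M9 replicate 2 (adjusted p = 0.0385) and was not called without C6M9 replicate 2 (0.228), with alternatives from 1.68e-33 without M9 replicate 1 to 0.687 with fry, and the cause was not tested.

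Of the differences in shares that moved by over 1 SD, those of the classes, the phases and the genes reported here follow, in points, C6M9 minus M9. With doublets kept they were -6.36 for TCR-activated-like cells, -27.1 for cluster 3, 2.27 for cluster 9, -3.53 for Cxcr5, 0.233 for Havcr2, 1.28 for Gzmb and 6.03 for S or G2M phase. With the stricter cell filter they were 2.48 for cluster 9, -17.2 for Slamf6, -1.97 for Cxcr5, -3.30 for Pdcd1, -0.401 for Havcr2, 1.36 for Gzmb, 0.0666 for Klrg1, 2.85 for Mki67 and 6.02 for the phases. Clusters from all variable genes gave -29.1 for cluster 3, 2.35 for cluster 9 and 30.8 for memory-like cells. Cluster 9 was at 2.12 with 1000 variable genes, 2.15 at resolution 1.2 and 2.05 without cycle genes. At 1000 UMIs the differences were -16.2 for Slamf6, 11.8 for Il7r, -1.71 for Cxcr5, -1.71 for Pdcd1, -11.2 for Tox, -9.19 for Lag3, 0.154 for Cx3cr1, -1.09 for Nr4a1, 2.35 for Mki67 and 4.92 for the phases. Not thinned they were -5.79 for Slamf6, 24.7 for Il7r, -10.2 for Cxcr5, -7.00 for Pdcd1, 2.70 for Havcr2, -20.6 for Lag3, 4.28 for Gzmb, 0.353 for Cx3cr1, 0.105 for Klrg1, 7.31 for Mki67 and 7.85 for the phases. Depth changes how often a transcript is seen; for the other settings the cause was not tested.

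With each library left out in turn, called genes ranged from 237 (without C6M9 replicate 1) to 1402 (without M9 replicate 1) over all T cells, 29 to 288 in memory-like, 4 to 125 in cluster 3, 474 to 1720 in TCR-activated-like, 50 to 192 in interferon-like, 40 to 711 in effector-like and 63 to 309 in cycling-like cells. The class-by-group count ranged from 500 to 961. Called lists ranged from 12 to 16, 6 to 10, 8 to 10, 14 to 16, 9 to 13, 10 to 11 and 11 to 18 in the same order. In memory-like cells the count was 288 without M9 replicate 1 and 134 without M9 replicate 2. In cluster 3 it was 125 without M9 replicate 1, 39 without M9 replicate 2 and 4 without C6M9 replicate 2. In interferon-like cells it was 192 without M9 replicate 2. In effector-like cells it was 711 without M9 replicate 1 and 40 without C6M9 replicate 1. In cycling-like cells it was 309 without M9 replicate 1, 184 without M9 replicate 2 and 63 without C6M9 replicate 2.

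Deviations of like-numbered libraries correlated at -0.0559 across genes, which are not independent replicates, so gene levels showed no pairing by replicate number. Depth did go with that number. The median UMIs per T cell were 13205 (M9) and 13993 (C6M9) in replicate 1, and 20024 and 21476 in replicate 2. A batch shared by like-numbered libraries is therefore not excluded. With a replicate block all the same, 840 genes were called over all T cells, 29 in cluster 3, 205 in effector-like and 191 in cycling-like cells; the cause was not tested.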

Other observations

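Further gene groups were compared within the classes; the list members named here were chosen after their values were seen. In cycling-like cells, of 28 cytokine receptor and JAK-STAT genes 3 rose and 1 fell in C6M9; adjusted over the list alone, 6 rose and 1 fell (camera adjusted p = 2.72e-08, but adjusted p = 0.482 with an estimated correlation). Itgax, a dendritic cell gene that activated T cells also express, rose in the same cells (log2 difference 2.77 ± 0.39, SE, n = 2 per group), 1 of 8 myeloid and dendritic cell genes; adjusted over the list alone, 2 rose (camera adjusted p = 0.0146, but adjusted p = 0.559 with an estimated correlation). In memory-like cells, of 26 cytokine receptor and JAK-STAT genes Il4ra alone rose; adjusted over the list alone, 7 rose (camera adjusted p = 1.06e-05, but adjusted p = 0.341 with an estimated correlation). In TCR-activated-like cells, of 18 naive and central memory genes 6 rose, among them Il7r (0.39) and Ly6c2 (1.55); adjusted over the list alone, 7 rose and 1 fell (camera adjusted p = 0.00151, but adjusted p = 0.295 with an estimated correlation).

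Cluster 9 held 331 cells, 117 and 12 in M9 and 134 and 68 in C6M9, with a median of 44328 UMIs. Its leading gene was Gzma, which encodes granzyme A, at 132-fold over the other cells. It was too small in M9 replicate 2 to compare between groups.

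Most receptor transcripts came from the V segments of the P14 receptor. Trbv13-3 gave between 91.6% (95% Wilson interval 90.8 to 92.5, M9 replicate 1) and 93.6% (92.8 to 94.3, C6M9 replicate 1) of Trbv UMIs, and Trav14-1 gave between 72.3% (70.8 to 73.8, M9 replicate 2) and 79.1% (78.1 to 80.1, C6M9 replicate 1) of Trav UMIs. Y-linked transcripts were abundant in every library and Xist was near 0: Ddx3y gave 3761 and 1727 UMIs in M9 and 2979 and 2928 in C6M9, and Xist gave 1 and 1, and 4 and 5.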
